A study of Homo sapiens with 2 samples.

How the data were processed

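The data were R-loop CUT&Tag peak lists from 2 samples of ISO-treated PC-3 cells, made with the S9.6 antibody, a protein A/G-Tn5 fusion and 12 PCR cycles, per the labels. Per the submitters' processing notes, FastQC 0.11.9, Trim Galore 0.6.7, Bowtie2 2.5.1 and MACS2 2.2.9.1 were used, with hg38 coordinates. Calling settings and any control library are not given in the sources used here. Each sample has its own deposited narrowPeak list, so peaks were called per sample. The authors' deposited columns hold a score, a fold enrichment (a ratio of pileup to local background), the −log10 of a p-value and of a q-value, and the summit offset. The lowest deposited −log10 q was 2.02 in either list. Folds were used to describe, rank and filter peaks within a list.

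Coverage was not among the values used. Pileup and background were recovered from the authors' deposited fold and −log10 p-value. Of 12 candidate formulas tried on 500 peaks, 1 matched all of them and the others matched at most 0.2%. It takes the fold as the pileup plus 1 over the background plus 1, with a Poisson p-value, and it gave a whole pileup in 100% of peaks of both lists within 0.0001 log10 units. The median pileups of 16 and 15 fragments limit how often a weak peak can be found again.

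Analysis used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9. Peaks overlapping by at least 1 bp were merged into shared regions. Chance was set by 1000 random placements with fixed seeds, on the same chromosome for overlap and location and over the whole genome for counts per chromosome. Scaffold peaks were left out of these (13 and 10), as only chromosomes 1 to 22 and X were used. Gene lists were compared with all other genes of the same class by two-sided Fisher's exact tests, adjusted by the Benjamini-Hochberg method over 21 lists.

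Several planned steps changed because the reference used was a gene table (RefSeq, GRCh38.p14) with 42021 genes used, of which 19974 are protein-coding, without strand, exons or sequence. Promoters became windows of 1 kb around either gene end, and the planned exon, intron and UTR classes became 5 classes. Placements covered the span from the first to the last annotated gene of each chromosome, as assembly gaps were not known here. Sequence composition, repeat content, the filter on repeat-rich peaks and matching on GC content were not run.

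Genes were named by a rule set before the data were examined. It takes the 20 named genes with a gene end within 1 kb of the shared regions that rank highest by mean percentile of fold within each list, 1 gene per region, up to 4 genes per list by the same ranking, the 5 highest regions of any kind, and the 3 strongest regions found in 1 replicate alone. A gene that the rule names is not reported here. HSPA5 falls outside it and was named to complete a count of 5. The lists were hybrid assay loci, ribosomal proteins, histones, immediate-early genes, heat shock, integrated stress response, p53 targets, R-loop regulators, DNA damage and repair, splicing factors, androgen receptor programme, epithelial and mesenchymal genes, other cell types, fragile site genes, prostate cancer drivers, ZNF genes, olfactory receptors, small structured RNAs, ribosomal RNA, transfer RNA and abundant long noncoding RNAs.

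The scripts were tested on simulated data. For overlap of simulated lists of 3000 peaks, 50.03% were found where 50% were planted. For annotation of 2000 simulated regions, the planted 41.55% at protein-coding gene ends was found. Of 200 simulated gene lists of 40 genes, 100% of those with 12 planted members and 5% of those with none were called. The model for finding peaks again predicted 59.11% in a simulated pair where 62.61% were called again. Neither the model nor the simulated pair included peak width. Alternatives covered −log10 q of at least 3 or 5, reciprocal overlap of 50%, a distance of 500 bp, placement within genes extended by 5 kb, a window of 3 kb, whole gene bodies and leaving out each replicate. Alternatives chosen after seeing the data were placement at protein-coding gene ends, regions with a mean fold of at least 8, random lists matched on 20 Mb windows, genes and regions outside windows rich in shared regions, and list genes that share a region counted once.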

Results

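R-loops, in which an RNA strand pairs with one strand of the DNA, were mapped by CUT&Tag with the S9.6 antibody against DNA-RNA hybrids in PC-3, a cell line from a human prostate carcinoma. The cells had received 30 µM of a compound labelled ISO for 24 h. The labels do not expand this abbreviation. The series held 2 samples, replicates 1 and 2 of 1 group. A DMSO mock is named in the protocol, and mock cells were not analysed here, so the values describe the treated cells and say nothing about an effect of ISO. The labels do not say whether the replicates came from separate cultures, so a spread between them may be technical. Replicate 1 had 3043 called peaks covering 720.1 kb and replicate 2 had 3380 covering 811.1 kb, a mean of 3211.5 ± 238.3 (SD, n = 2). The median summit pileup, recovered from the authors' fold enrichment and p-value, was 16 fragments in replicate 1 and 15 in replicate 2, with interquartile ranges of 12 to 21 in both. Intervals given here cover counting error only.

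SRGAP2, a regulator of neuronal and cell membrane protrusion, carried the strongest peak at a gene end, with a fold enrichment of 17.2 ± 1.02 (SD, n = 2) on chromosome 1 from 206202957 to 206203298 (hg38). The sequence has near-identical copies and also lies within FAM72A, so its position is uncertain. Next came ENSA, an inhibitor of a mitotic phosphatase, at 13.5 ± 0.0640 (chromosome 1, 150629213 to 150629495), and SEH1L, a nuclear pore component, at 13.99 ± 1.09 (chromosome 18, 12947891 to 12948151). The transcription elongation factor gene ELL reached 13.4 ± 1.16 (chromosome 19, 18522143 to 18522549), and TMEM53 reached 13.3 ± 0.193. The order follows ranks within each list. Also among the 20 leading genes were the methyltransferase genes CARM1 (12.0 ± 1.96) and PRMT2 (10.7 ± 0.424), the splicing factor gene SF1 (11.6 ± 0.712), the corepressor gene TRIM28 (11.5 ± 1.85), the ubiquitin ligase genes RBX1 (11.1 ± 0.171) and RNF31 (11.05 ± 0.922), and RAB1A (10.9 ± 0.617), a GTPase gene of the secretory pathway. NT5C3A, SLC27A1, HDGFL2, NMT1, PRKCSH, ATF7, EEF2KMT and VMAC completed them, with mean folds between 10.99 and 12.9. SLC27A1 was not kept when replicate 2 was left out, and SLC27A1 and RBX1 were not kept at a reciprocal overlap of 50%.

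Of the peaks on chromosomes, 1790 of 3030 in replicate 1 (59.1%) overlapped a replicate 2 peak by at least 1 bp, and 1790 of 3370 in replicate 2 (53.1%) overlapped a replicate 1 peak. Random placement of the replicate 2 peaks gave a mean of 1.56 overlapping peaks and at most 7 in 1000 placements (one-sided permutation p = 0.001, the smallest these placements can give). Only 28 peaks had identical coordinates in both lists. The overlapping peaks merged into 1767 shared regions, over which the 2 replicates' fold enrichments had a Spearman rho of 0.61 and their pileups one of 0.81. These are across regions, which are not independent replicates. At the 272 shared regions with a summed pileup of at least 60, the squared difference of the pileups over their sum averaged 0.664. Independent counts at a fixed position without selection give about 1. These pileups are summit values, so the comparison does not decide whether the libraries are independent. No other pair of replicates was there to compare. The files were not identical, and the 2 libraries were kept as 2 samples.

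Strong peaks were shared far more often than weak ones. In replicate 1, 79.8% of the peaks in the highest quartile of fold enrichment overlapped a replicate 2 peak, against 49.7% in the lowest (Fisher's exact test, two-sided, p = 4.77e-35). In replicate 2 the shares were 77.9% and 38.4% (same exact test, p = 2.93e-62). Ranked by −log10 q instead, the highest and lowest quartiles gave 91.0% and 34.0% in replicate 1 and 88.97% and 26.6% in replicate 2. The tests treat peaks of 1 pair of libraries as independent, so their p-values do not measure variation between samples. Both lists hold only called peaks, so peaks near the calling threshold can drop out of the other list more easily. Peaks found in 1 list alone had a median pileup of 13 fragments in either replicate, and overlapping peaks had 19. The strongest peaks of replicate 2 alone lay near FAM168A (fold 13.3), SPTLC2 (10.5) and ARRB2 (10.5). In replicate 1 alone, 1 of the 3 strongest lay near ZNF410 (10.3), and the others lay on chromosome 15 from 72670751 to 72670913 and on chromosome 8 from 85742305 to 85742499 (10.7 each).

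**Figure D1:**
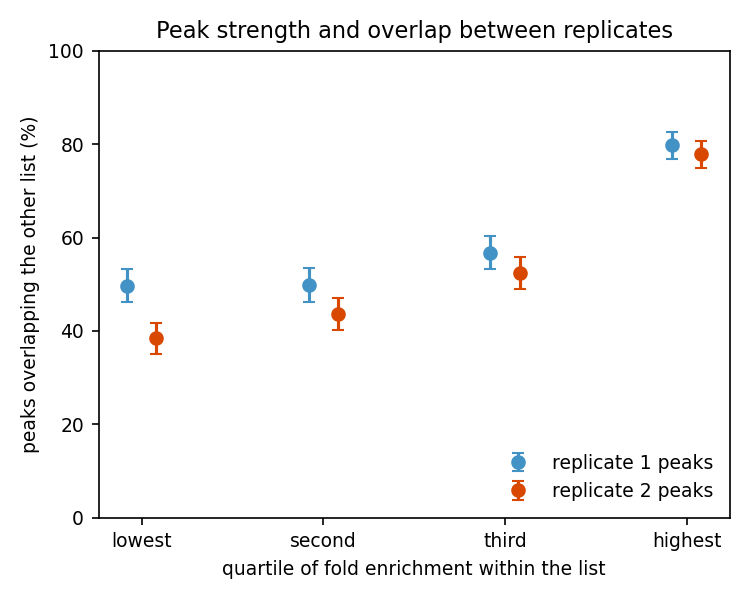
Share of peaks (%) that overlapped the other replicate's list, by quartile of the authors' fold enrichment within the list, with points for replicates 1 and 2 and bars for 95% Clopper-Pearson intervals. The highest quartile reached 79.8% and 77.9%.

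Ends of protein-coding genes held 910 of the 1767 shared regions within 1 kb, or 51.5% (95% Clopper-Pearson interval 49.1 to 53.9), against 2.39 ± 0.360% of randomly placed regions. Another 115 regions (6.51%) lay near an end of a noncoding gene, against 2.28% placed. Fewer regions than placed lay inside protein-coding genes (499, 28.2% against 39.5%), inside other genes (47, 2.66% against 11.3%) and outside annotated genes (196, 11.1% against 44.5%). All 5 classes differed from placement (two-sided permutation test, adjusted p = 0.002, the smallest these placements can give). They are not separate results, since each region counts in 1 class only and ends of protein-coding genes come first. The excess there lowers the other shares by itself, so the lower shares do not show that gene bodies lack peaks. Over all peaks of each list, protein-coding gene ends held 47.5 ± 0.917% (SD, n = 2). Peaks found in both lists lay there more often than peaks found in 1 list alone, 51.8% against 42.8% in replicate 1 (Fisher's exact test, two-sided, p = 1.05e-06) and 51.5% against 41.6% in replicate 2 (p = 9.15e-09). Here too the tests treat peaks as independent. The annotation used gave no strand, so a gene end may be its start or its 3′ end. The excess at protein-coding gene ends was 21.5-fold, and 12.9-fold when placement was limited to genes extended by 5 kb and 9.04-fold with a window of 3 kb. At ends of other genes it was 2.85-fold, 1.70-fold and 1.29-fold. With placement in extended genes the share inside protein-coding genes went from 0.714-fold to 0.431-fold, that inside other genes from 0.236-fold to 0.142-fold, and that outside genes lay 1.38-fold above placement. No control library was among the samples. How far the excess at gene ends, and the gene list results below, reflect DNA-RNA hybrids rather than other sources of signal was therefore not tested.

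**Figure D2:**
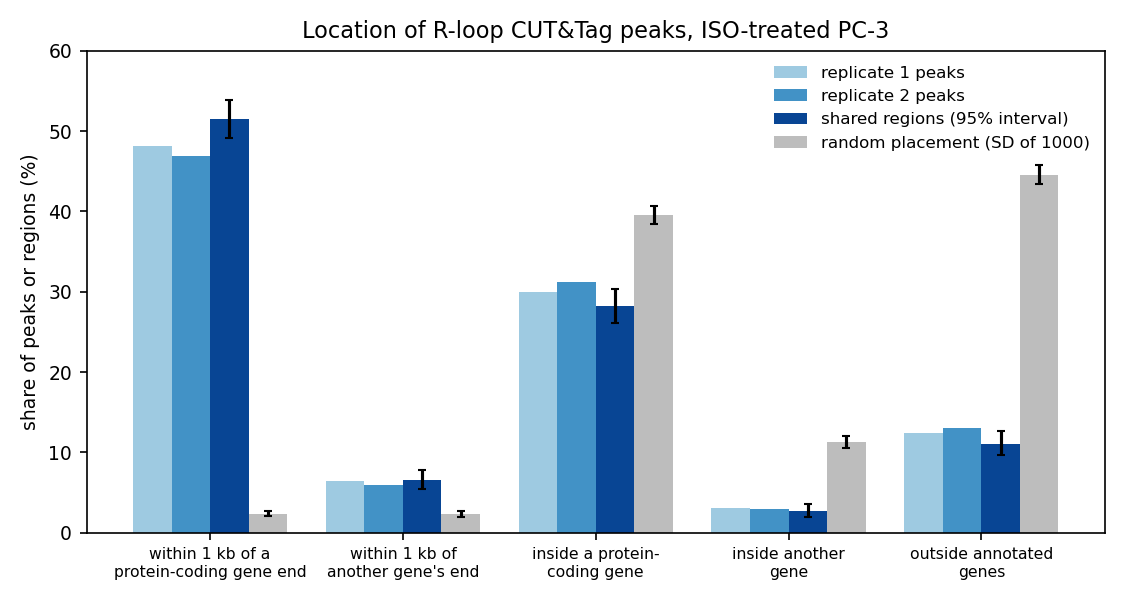
Share (%) of replicate 1 peaks, replicate 2 peaks and shared regions in 5 location classes beside the mean of 1000 random placements, with bars for the 95% interval of shared regions and the SD of placements. Protein-coding gene ends held 51.5% of shared regions and 2.39% of placed ones.

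The 4 positions that ranked highest of any kind lay outside annotated genes. They were on chromosome 3 from 93470358 to 93470719 (fold 28.7 ± 0.774), on chromosome 1 from 125180076 to 125180319 (27.9 ± 0.00429), on chromosome 21 from 8234153 to 8234646 (26.6 ± 0.466), 15097 bp from the ribosomal RNA gene RNA45SN2, and on chromosome 21 from 8420378 to 8420581 (16.7 ± 0.477), 12050 bp from MIR6724-4. The SRGAP2 region was the fifth. No filter on repeat-rich peaks was run, so multi-copy sequence as a source of these positions was not excluded.

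Genes of small structured RNAs, heat shock genes and splicing factor genes lay at shared regions more often than other genes. Among the small RNA genes, which include spliceosomal and signal recognition particle RNAs, 11 of 54 had a shared region within 1 kb, against 3.60% of all other genes (Fisher's exact test, two-sided, odds ratio 6.84, 95% interval 3.18 to 13.5, adjusted p = 3.28e-05). The hit rate was 5.65 times that of all other genes. The count was 3.70 times that of random lists matched on 20 Mb window (permutation test, adjusted p = 0.0021), an alternative chosen after seeing the data. RNVU1-15 had a fold of 8.33 ± 0.467, RPPH1, the RNA of RNase P, 7.59 ± 0.846, RNU12 7.38 ± 0.599 and RN7SL2 7.27 ± 1.69. Several of these genes have near-identical copies, and 5 of their 12 regions also lay within 1 kb of a protein-coding gene end, among them the RPPH1 region, which it shares with the repair gene PARP2. Among heat shock and chaperone genes, 5 of 19 were hit, against 5.72% of other protein-coding genes (Fisher's exact test, odds ratio 5.89, 1.66 to 17.3, adjusted p = 0.0191). They were HSPA8 (9.46 ± 0.463), HSPD1 and HSPE1, which share 1 region (8.33 ± 1.70), HSP90AA1 (6.62 ± 0.182) and HSPA5 (5.08 ± 0.0484). With genes that share a region counted once the adjusted p was 0.0696, and with a reciprocal overlap of 50% it was 0.0575. Among splicing factor genes, 9 of 46 were hit (Fisher's exact test, odds ratio 4.02, 1.70 to 8.51, adjusted p = 0.00734), including RBM39 (10.6 ± 1.87), HNRNPA2B1 (8.51 ± 1.68), SNRNP70 (8.02 ± 1.15) and HNRNPA1 (7.56 ± 1.15). Outside the 20 Mb windows rich in shared regions, the adjusted p for splicing factors was 0.0569.

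Olfactory receptor genes, which most cell types do not transcribe, were hit in 0 of 390 cases, where 22.4 were expected (Fisher's exact test, two-sided, adjusted p = 3.13e-09). No other list passed the threshold. Replication-dependent histone genes were hit in 0 of 69 cases (Fisher's exact test, adjusted p = 0.0880) and markers of other cell types in 0 of 33 (0.421). Histone genes passed the threshold over all replicate 1 peaks, with 0 of 69 (Fisher's exact test, adjusted p = 0.0179), and not over all replicate 2 peaks, with 2 of 69 (0.132). At shared regions, the matched random lists put the expected number of histone hits at 1.51 (permutation test, adjusted p = 0.632). Genes of common fragile sites were hit in 0 of 24 (0.572), integrated stress response genes in 0 of 17 (0.699) and ribosomal RNA genes in 0 of 33 (0.699).

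DNA damage and repair genes were hit in 6 of 38 cases (Fisher's exact test, adjusted p = 0.0704), with PARP2 at 7.59 ± 0.846, the damage kinase gene ATM at 7.35 ± 0.862 and CHEK2 at 6.01 ± 0.560. Outside the 20 Mb windows rich in shared regions, 6 of 34 were hit (Fisher's exact test, adjusted p = 0.0145). Those windows were chosen with the same regions, so leaving them out lowers the rate of other genes by itself. The count was 2.84 times that of random lists matched on 20 Mb window (permutation test, adjusted p = 0.129). Both alternatives were chosen after seeing the data. Canonical p53 targets were hit in 4 of 20 (Fisher's exact test, adjusted p = 0.0750). They were PLK3 (10.5 ± 1.28), RRM2B (9.98 ± 0.543), TP53I3 (8.06 ± 1.01) and FDXR (6.21 ± 0.247). PC-3 lacks functional p53. Abundant long noncoding RNA genes were hit in 4 of 27 (0.0651), with ZFAS1 at 10.3 ± 0.0475, GAS5 at 8.36 ± 0.913, MALAT1 at 5.85 ± 1.51 and SNHG1 at 5.73 ± 0.802. Over all peaks of either replicate 5 of 27 were hit (Fisher's exact test, adjusted p = 0.0467 in replicate 2 and 0.0522 in replicate 1). Ribosomal protein genes were hit in 9 of 81 (0.117), in 17 of 81 over all replicate 2 peaks (Fisher's exact test, adjusted p = 0.00655) and in 11 of 81 over all replicate 1 peaks (0.219), including RPL7 (7.83 ± 1.296), RPL36AL (7.13 ± 1.07), RPL28 (7.12 ± 0.158) and RPL10 (7.09 ± 0.116).

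Epithelial and mesenchymal genes were hit in 4 of 30 cases (Fisher's exact test, adjusted p = 0.190), namely LGALS1 (7.99 ± 1.001), VIM (5.51 ± 0.228), ITGB1 (5.05 ± 0.580) and PLAU (3.60 ± 0.0119). Over all replicate 2 peaks 8 of 30 were hit (Fisher's exact test, adjusted p = 0.0187) and over all replicate 1 peaks 6 of 30 (0.0995). Loci often used in hybrid assays were hit in 2 of 11 (0.245), BTBD19 at 7.92 ± 0.986 and VIM, in 4 of 11 over all replicate 2 peaks (Fisher's exact test, adjusted p = 0.0393) and in 2 of 11 over all replicate 1 peaks (0.394). Genes recurrently altered in prostate cancer were hit in 3 of 28 (0.376), with CHD1, a chromatin remodeller gene, at 8.23 ± 0.443, SPOP at 7.70 ± 0.752 and CDK12 at 6.94 ± 1.54. R-loop regulators were hit in 3 of 33 (0.572), with NPM1 at 8.78 ± 0.202, DDX5 at 6.71 ± 0.0653 and SRSF1 at 5.88 ± 0.538. ZNF-named zinc finger genes were hit in 32 of 509 (0.695), led by ZNF250 (9.98 ± 0.261), ZNF837 (9.92 ± 1.53), ZNF791 (9.25 ± 1.96) and ZNF695 (8.77 ± 0.231). Transfer RNA genes were hit in 12 of 425 (0.572), at 9 regions, and in 38 of 425 over all replicate 2 peaks against 19 over all replicate 1 peaks (Fisher's exact test, adjusted p = 0.0387 and 0.550). Genes near the same peak were each counted, so the test may overstate the replicate 2 result. TRK-TTT3-1 and TRK-TTT3-2 share 1 region (7.92 ± 1.08), as do TRY-GTA2-1 and TRA-AGC8-1 (6.94 ± 1.77). The androgen receptor programme was hit in 1 of 19 (Fisher's exact test, adjusted p = 1), NDRG1 at 6.47 ± 0.998, and immediate-early genes in 1 of 25 (1), JUND at 6.45 ± 0.146.

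**Figure D3:**
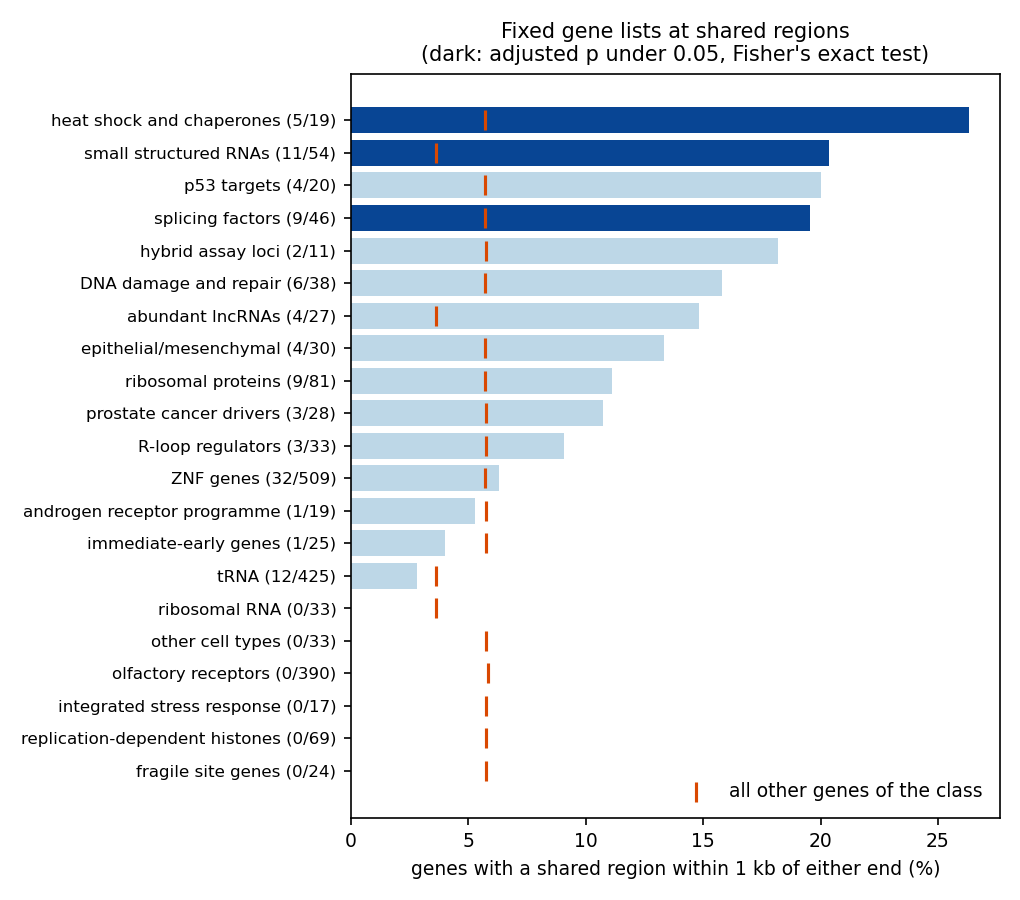
Share (%) of each fixed gene list with a shared region within 1 kb of either gene end, with hits and members beside each name and a mark for all other genes of the class. Dark bars had an adjusted p under 0.05, among them small structured RNAs with 11 of 54, and olfactory receptors were the called list with 0 of 390.

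Chromosomes 19, 17 and 14 held the largest excess of shared regions over whole-genome placement. Chromosome 19 had 204 regions where 33.8 were placed (6.04-fold), chromosome 17 had 145 (2.98-fold), chromosome 14 had 130 (2.09-fold) and chromosome 10 had 125 (1.61-fold). In all, 8 of 23 chromosomes were above placement and 9 below (two-sided permutation test, adjusted p under 0.05). The lowest were chromosomes 13 (0.195-fold), 4 (0.215-fold) and X (0.254-fold). When regions were placed at protein-coding gene ends instead, chromosomes 14 (2.43-fold), 10 (1.85-fold) and 19 (1.63-fold) led, and 6 chromosomes were above and 9 below. Chromosomes 1, 11, 20 and 22 were then no longer called above placement, with chromosome 11 going from 1.26-fold to 0.898-fold, while chromosomes 3 and 8 were called. Among those below placement, chromosomes 12 and 16 replaced chromosomes 2 and 18. Recovered local background differed too, with a median of 3.57 fragments at shared regions of chromosome 10. PC-3 cells are aneuploid, and copy number, which can move the counts per chromosome, was not measured. With regions of a mean fold of at least 8 alone, 4 chromosomes were above whole-genome placement and 5 below. Against placement of such regions at protein-coding gene ends, only chromosome 19 was called above (2.24-fold). Only chromosomes 6 (0.118-fold) and X (0.213-fold) were called below (two-sided permutation test, adjusted p = 0.0153 each).

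**Figure D4:**
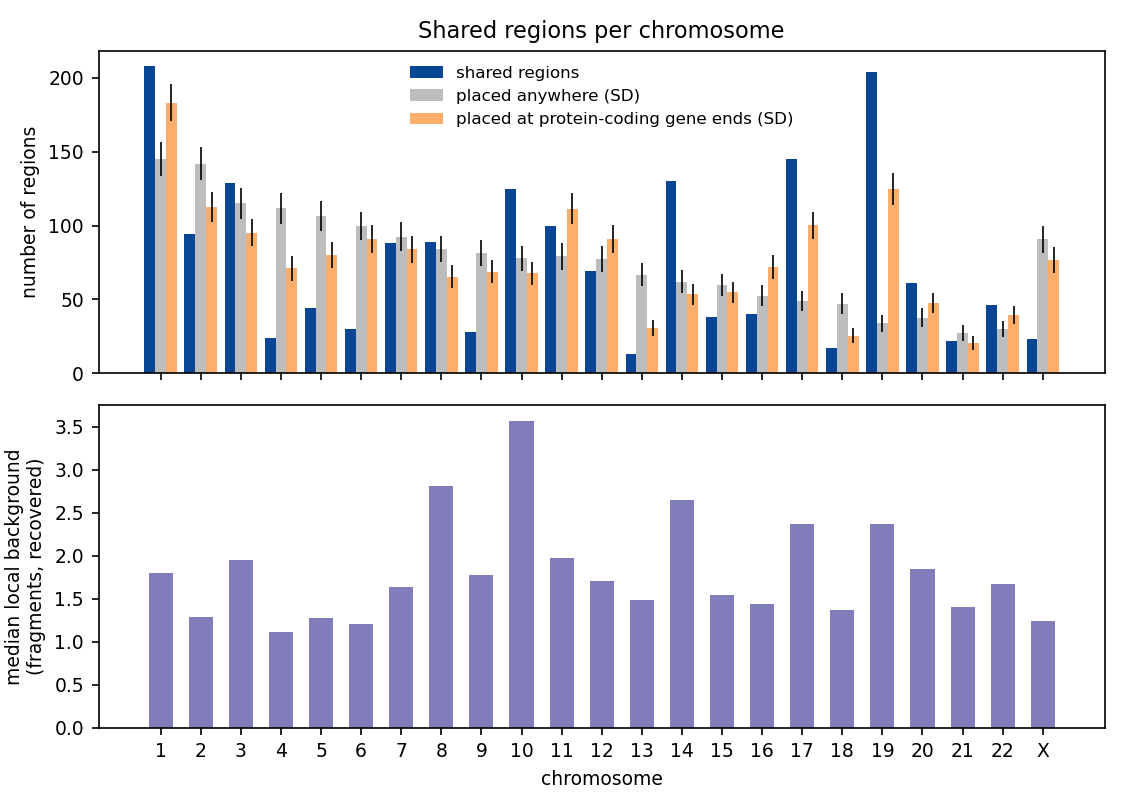
Number of shared regions per chromosome beside the mean number placed anywhere and at protein-coding gene ends (bars, SD of 1000 placements), with the median recovered local background (fragments) at shared regions underneath. Chromosome 19 had 204 regions where 33.8 were placed anywhere, and chromosome 10 had a background of 3.57.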

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

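Peaks on unplaced, unlocalised and alternate scaffolds were outside the main measurement, and both lists held some, 13 in replicate 1 and 10 in replicate 2. The strongest lay on the unplaced scaffold KI270467v1, with a fold of 20.8 in replicate 1 and 21.1 in replicate 2. No control sample was analysed here to set a level for them.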

How the results depend on the processing

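The overlap beyond placement, the difference between fold quartiles and the location classes kept their direction and side of the threshold under the alternatives run, with 1 exception. Placement within annotated genes extended by 5 kb turned the share outside genes to 1.38-fold above placement, since that placement leaves little room outside genes. The number of gene lists hit more often than other genes (3 in the main setting) was 6 with a window of 3 kb and 5 with gene bodies, and ranged from 3 to 8 when a replicate was left out, the 8 coming without replicate 1. The number hit less often (1) was 2 with a window of 3 kb and 2 with gene bodies, and ranged from 1 to 2 when a replicate was left out. Heat shock genes, with 4.60 times the hit rate of other genes in the main setting, lost their call at a reciprocal overlap of 50% (4.46 times) and, chosen after seeing the data, with genes sharing a region counted once (3.89 times). Splicing factors, at 3.43 times in the main setting, lost theirs outside the raised 20 Mb windows (3.49 times), also chosen later, where fewer members were tested. Chosen after seeing the data, regions with a mean fold of at least 8 gave 4 chromosomes above and 5 below whole-genome placement, where all regions gave 8 and 9. The cause of these changes was not tested. Of the 69 named genes, 62 were kept at −log10 q of at least 5, 59 at a reciprocal overlap of 50%, and 68 without replicate 2. The filter on repeat-rich peaks, matching on GC content, and sequence composition and repeat content under any setting were not run. Low pileups can limit how often weak peaks are found again. No paired analysis was possible because the samples form 1 group.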

Other observations

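The transcriptional coactivator gene ZMIZ1 held 8 shared regions within its body, the potassium channel gene KCNMA1 held 6, and BCAR3, DENND3, DPF3 and NRP1 held 4 each. Genes of actin anchoring and cell adhesion were among those with 3, including ACTN1, VCL, PXN and ITGA3, as were LMNA and SEPTIN9. These genes were picked after their values were seen and not tested as a group, and ZMIZ1, KCNMA1, DENND3, DPF3, ACTN1, VCL, ITGA3 and SEPTIN9 lie in the 20 Mb windows described next.

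The tests in this part were chosen after the result was seen, except the test of regions with a mean fold of at least 8 across windows and the first test of peaks found in 1 replicate alone. The test of wide peaks was reworded to need both replicates after its values were seen. No biological explanation was tested, since the samples form 1 group.

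Shared regions were concentrated in 10 of 163 windows of 20 Mb, among them chromosome 10 from 60 to 80 Mb, with 35 of 120 protein-coding genes hit, chromosome 14 from 40 to 60 Mb, with 30 of 89, and chromosome 19 from 0 to 20 Mb, with 85 of 615. Another 7 windows had a lowered hit rate, among them chromosome 6 from 20 to 40 Mb, with 5 of 358. The 10 raised windows held 36.2% of shared regions and 14.5% of protein-coding genes. Of regions with a mean fold of at least 8, 29.3% lay there, which decides nothing about a detection limit, as the windows were chosen with the same regions. On chromosome 19 such regions were 2.24-fold above placement at gene ends (two-sided permutation test, adjusted p = 0.0153 over 23 chromosomes). A detection limit alone predicted no such excess, but the test cannot exclude it. The fold adds 1 to both pileup and background, so at equal enrichment a higher background lifts it past 8 more easily. The median background at shared regions was 2.37 fragments there. On chromosome 10 the ratio to placement at gene ends was 0.712, as a detection limit predicts. That does not decide the cause, since the chromosome was chosen for its excess of the same regions. The ratio was 1.58 on chromosome 3, 0.992 on chromosome 8, 1.72 on chromosome 14 and 1.10 on chromosome 17, where the counts were too few to decide. Hit rate across the 118 windows with at least 3 shared regions went with local background (Spearman rho 0.38, permutation p = 0.0001) and not detectably with fold (rho 0.00828, p = 0.929). More background reads per locus, as gained copies would give, stays a candidate explanation, though copy number was not measured. The correlation does not decide it, since background was recovered only at shared regions and may include reads of the peaks themselves.

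A model of counting noise at this depth assumed equal true enrichment and took no account of peak width. It predicted that 79.2% of replicate 1 peaks would be called again in replicate 2, and 59.1% were. For replicate 2 peaks, 79.6% were predicted and 53.1% were called again in replicate 1. Among peaks at least 280 bp wide, 89.4% were predicted and 80.2% found again for replicate 2, and 90.3% and 85.8% for replicate 1. The observed shares lay below the predicted ones, but setting 1 pair of samples against counting noise decides nothing about either explanation, since any variation between samples lowers the observed share. Width may contribute, since at a predicted share of at least 90%, 56.9% of replicate 1 peaks at most 150 bp wide were found again, against 95.1% of those at least 280 bp wide.

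Among the 10 strongest shared regions, 4 lay near a protein-coding gene end, against 51.6% of the other 1757 (Fisher's exact test, two-sided, p = 0.537). Multi-copy sequence as their source cannot be told apart from chance with 10 regions and no genome sequence used here. The recovered backgrounds were whole multiples of 1 step within 0.1 steps, and the step times 20000 was 139.8 bp in replicate 1, near the smallest peak width of 139 bp, which is consistent with a background taken from the library's own reads in a 10 kb window. The background at 1754 shared regions was 1.05 times as high in replicate 1 as in replicate 2 (95% bootstrap interval 1.04 to 1.06), where the ratio of library sizes was 1.0003. This ratio differs from that of the library sizes, but 1 pair of samples set against sampling of fragments does not decide what separates them.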
